A study of Candidozyma auris with 8 samples.

How the data were processed

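RNA was sequenced from liquid cultures of the yeast Candida auris (listed by the archive as Candidozyma auris), with and without the triazole antifungal isavuconazole. Per the labels' protocols, 2 isolates of the same lineage were used, a non-wild-type (non-WT) isolate with a median minimum inhibitory concentration (MIC) above 2.0 mg/L and a wild-type (WT) isolate with a median MIC of 0.06 mg/L. The classes refer to a tentative epidemiological cutoff of 1 mg/L. Cultures grew in YPD broth at 37 °C for 4 h, received isavuconazole at 0.015 mg/L and were collected after 4 h of exposure, or grew untreated. When the untreated cultures were collected, and whether they received the drug's solvent, is not stated here. Any difference in culture age or solvent would be part of the changes described below as those of isavuconazole. The labels state 2 biological replicates per group, and total RNA from lyophilized cells went into TruSeq RNA libraries. The submitters' processing notes name FastQC and DESeq without versions. The aligner, the counting tool and its strand setting, and the genome build are not given in the sources used here.

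The authors deposited a single table of 5417 genes with estimated counts for the 8 libraries, headed as raw per the file headers. These values are fractional, and between 32.5% and 41.3% of those under 200 were multiples of 1/76 within a tolerance of 0.01 of that unit, where 2.0% would be by chance. The deposited log2 values, headed as normalized per the file headers, equalled log2 of the estimated count plus 1 constant per library, with a largest deviation of 1.77e-06, and stood at 0 where that sum was below 0. In 95 genes, 96 of the 43336 estimated counts stood as calendar dates and were recalculated from the log2 value of the same gene and library. All 96 recalculated values matched a reading of the date within a relative difference of 6.06e-07. A date in place of 1 log2 value was restored from its estimated count in the same way. The estimated counts were then rounded to whole numbers.

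The table gives each gene's identifier, scaffold, start, end and strand, and its symbol column repeats the identifier for all 5417 genes. The reference table used here, of the assembly ASM301371v2, lists 5494 genes under other tags, and 0 of the 5417 identifiers matched it. Genes are therefore given by identifier, with at most 2 per direction and comparison. The members of the 35 gene lists fixed before the data were examined could not be matched to identifiers. No list could be tested, and list members may be among the genes measured. Positions are as deposited. Reads shared between near-identical copies could not be examined, because neither sequences nor the counting settings were used here. The genes named by the rule below overlap no other gene of the table.

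Counts were analysed with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Genes were kept by filterByExpr with the group as factor, which left 5406 genes and removed 11. TMM factors were computed, and 1 model of 4 group means was fitted to all 8 libraries with glmQLFit, with 4 residual degrees of freedom per gene. The common biological coefficient of variation was 0.0707. Each comparison was tested with the two-sided quasi-likelihood F test (glmQLFTest) and Benjamini-Hochberg adjustment over all genes tested, with a threshold of adjusted p 0.05. The comparisons were isavuconazole against no drug in each isolate, the difference between these effects (interaction), and the non-WT against the WT isolate without and with drug. Standard errors of log2 fold changes are the fold change divided by the square root of F. CPM values use TMM-scaled library sizes, and SDs are over 2 libraries. The identifiers named were those with the largest positive and negative log2 fold change past the threshold, with a mean of at least 50 counts in a group and, outside the interaction, with both libraries of a group above both of the other. This rule, the design and most alternatives were fixed before the data were examined. A count of 0 was given a limit of 3 counts per library, which covers counting error only.

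Total estimated counts ranged from 14.5 M to 24.3 M per library. Replicates of a group differed by more than sampling noise, with a chi-square of 8.00 to 29.7 per degree of freedom across genes, so none were counted as 1 library.

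The fitting function was tested on simulated counts with 200 changed genes per comparison, drawn from the measured means, library sizes and dispersions. Among 67 genes changed by a factor of 1.5, it recovered 61 for the drug effect in the non-WT isolate over 5405 genes, 60 for that in the WT isolate over 5406 genes, 35 for the interaction over 5406 genes, 61 for the untreated isolate comparison over 5406 genes and 59 for the treated one over 5404 genes. Among 67 genes changed by a factor of 2, it recovered 66 for the drug effect in the non-WT isolate and 67 in each of the other comparisons. All 66 genes changed by a factor of 4 were recovered in every comparison. The changed genes were drawn from those with a mean of at least 50 counts, and each gene varied independently. In the data the interaction test called 24 genes, so the adjusted threshold was stricter there than with 200 changed genes. Recovery of interaction genes in the data can therefore be lower. False calls made up 8.96% of calls for the drug effect in the non-WT isolate, 5.85% in the WT isolate, 5.08% for the interaction, 4.43% for the untreated and 2.54% for the treated isolate comparison.

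Alternatives were RLE factors, library size alone, upper quartile factors, DESeq2 1.42.0, limma-voom, other count filters, a replicate block, the 4 libraries of a comparison alone, a fold change of at least 1.5, glmTreat and leaving out each library. Chosen after the data were seen were limma-trend on the deposited log2 values, thinning to the smallest library, leaving out genes with a restored count, and a crossed replicate block.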

Results

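Transcript levels were measured by RNA sequencing in a non-WT and a WT isolate of Candida auris, each untreated and after 4 h with 0.015 mg/L isavuconazole, an inhibitor of ergosterol synthesis. The dose was 25% of the WT isolate's MIC and below 0.75% of the non-WT isolate's. Each of the 4 groups held 2 libraries. The estimated counts totalled 15.1 ± 0.62 M in the untreated and 14.8 ± 0.47 M in the treated non-WT isolate, and 16.6 ± 0.37 M in the untreated and 23.4 ± 1.23 M in the treated WT isolate (mean ± SD, n = 2). On a principal component analysis of log2 CPM, the first component held 77.0% of the variance and parted the isolates, and the second held 13.7% and parted treated from untreated libraries. The median SD between replicates was 0.06 on the log2 scale in the untreated and 0.05 in the treated non-WT isolate, and 0.09 and 0.07 in the WT isolate. The deposited table does not pair its identifiers with gene names, so genes are given by identifier and position.

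The first comparison asks what isavuconazole changed in the non-WT isolate. Of 5406 genes, 509 rose and 514 fell. Most changes were small, with a median of 1.36-fold among the genes that rose and 1.35-fold among those that fell. A change of at least 2-fold was reached by 39 genes that rose and 5 that fell. The genes that rose held 12.2% ± 0.08 of all counts without drug and 17.3% ± 0.24 with drug (SD, n = 2), and those that fell held 6.0% ± 0.15 and 4.25% ± 0.03. The largest rise was that of B9J08_003026, on scaffold 1 from 910738 to 912063 on the plus strand, which went from 181 ± 4.97 to 887 ± 155 CPM, a log2 fold change of 2.29 (SE 0.13, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 6.74e-06). B9J08_000367, on scaffold 4 from 742437 to 743410 on the minus strand, rose from 135 ± 6.26 to 612 ± 70.2 CPM, a log2 fold change of 2.19 (SE 0.11, edgeR adjusted p = 4.40e-06). The largest fall was that of B9J08_002720, on scaffold 1 from 304583 to 305314 on the minus strand, from 6.02 ± 0.28 to 2.16 ± 0.16 CPM, a log2 fold change of -1.47 (SE 0.21, edgeR adjusted p = 0.00132). B9J08_000685, on scaffold 3 from 379484 to 381082 on the plus strand, fell from 18.7 ± 2.52 to 8.07 ± 1.09 CPM, a log2 fold change of -1.21 (SE 0.20, edgeR adjusted p = 0.00265). All 4 genes also passed the threshold in the same direction in the WT isolate. The genes that rose made up 49.8% of those that changed with TMM factors and 23.7% with library size alone, where 341 rose and 1098 fell. A fit of the 4 non-WT libraries alone gave 804 genes that rose and 764 that fell. Leaving out a non-WT library lowered the count of genes that changed, to 597 and 392 without untreated replicate 1 or 2 and to 391 and 351 without treated replicate 1 or 2, with 1 library of that group assumed to vary like the other groups.

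The same question was asked of the WT isolate. Here 752 genes rose and 684 fell, with medians of 1.32-fold in both directions, and 26 genes that rose and 15 that fell changed at least 2-fold. The genes that rose held 13.8% ± 0.33 of all counts without drug and 18.9% ± 0.03 with drug, and those that fell held 12% ± 0.96 and 8.58% ± 0.19. B9J08_003910, on scaffold 1 from 2763668 to 2764837 on the plus strand, rose from 72.7 ± 4.53 to 345 ± 14.1 CPM, a log2 fold change of 2.25 (SE 0.09, edgeR adjusted p = 9.45e-07). B9J08_001012, on scaffold 3 from 1119185 to 1120216 on the minus strand, rose from 8.13 ± 1.5 to 37.9 ± 1.1 CPM, a log2 fold change of 2.22 (SE 0.19, edgeR adjusted p = 6.99e-05). The largest fall was that of B9J08_002250, on scaffold 9 from 36115 to 37686 on the plus strand, from 236 ± 42.0 to 49.4 ± 5.72 CPM, a log2 fold change of -2.26 (SE 0.25, edgeR adjusted p = 0.000330). B9J08_003099, on scaffold 1 from 1036830 to 1037822 on the plus strand, fell from 49.0 ± 2.02 to 12.2 ± 1.30 CPM, a log2 fold change of -2.0 (SE 0.21, edgeR adjusted p = 0.000253). Of these 4 genes, 3 also changed in the same direction in the non-WT isolate, while B9J08_002250 had a log2 fold change there of -0.68 (SE 0.23, edgeR adjusted p = 0.0674), and the difference between its effects in the 2 isolates did not pass the threshold either (edgeR interaction, adjusted p = 0.0738). The genes that rose made up 52.4% of those that changed with TMM factors, 41.7% with library size alone and 42.3% with upper quartile factors. Without treated WT replicate 1, 485 genes rose and 416 fell, and without treated replicate 2, 547 rose and 452 fell. A fit of the 4 WT libraries alone gave 462 genes that rose and 406 that fell.

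**Figure D1:**
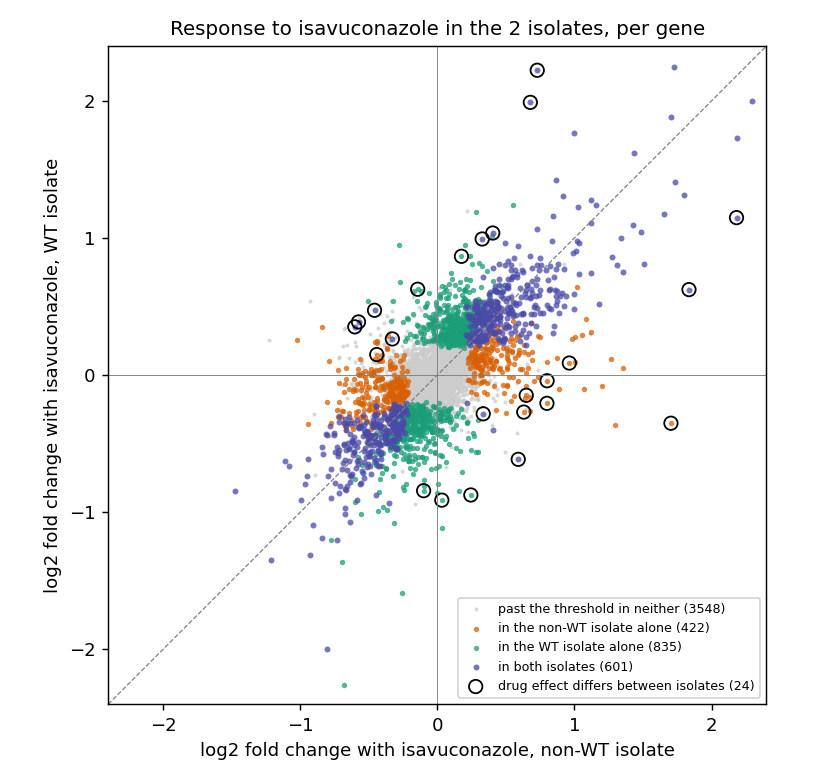
Each point is 1 of 5406 genes, with its log2 fold change after isavuconazole in the non-WT isolate on the x axis and in the WT isolate on the y axis; colours give the isolates in which it passed an adjusted p of 0.05, rings the 24 genes whose effect differed between isolates, and the dashed line equal effects. Most genes that changed in both isolates lie in the lower left and upper right quadrants, with 318 that rose and 275 that fell in both and 8 that went in opposite directions.

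The series title calls the response isolate specific, so the lists of the isolates were compared and the difference in effect was tested gene by gene. The same 318 genes rose in both isolates, where 70.8 would be shared by independent lists, and the same 275 fell in both, where 65.0 would be (Fisher's exact test, two-sided, p = 4.46e-166 and 1.35e-128, Benjamini-Hochberg adjusted over 4 such tests 1.79e-165 and 2.69e-128; genes are not independent replicates). The genes that rose in both had median log2 fold changes of 0.48 in the non-WT and 0.49 in the WT isolate, and those that fell in both had medians of -0.45 and -0.44. In opposite directions, 4 genes rose in the non-WT and fell in the WT isolate and 4 did the reverse, where independent lists would share 64.4 and 71.5. Leaving out a non-WT library lowered the genes that rose in both to 172 without untreated replicate 2 and to 179 and 152 without treated replicate 1 or 2. It lowered those that fell in both to 175 and 97 without untreated replicate 1 or 2 and to 91 and 82 without treated replicate 1 or 2. Library size alone gave 504 that fell in both. Without untreated WT replicate 2, 33 genes went in opposite directions. Across the 5406 genes, the log2 fold changes of the isolates, which share no library, had a Pearson r of 0.65 and a Spearman rho of 0.62. Another 422 genes changed in the non-WT isolate alone and 835 in the WT isolate alone, and passing in a single isolate does not show a difference. The test of the difference called 24 genes at adjusted p values of 0.0246 or more. The signed log2 fold change was higher in the non-WT isolate for 13 of them and lower for 11. Higher does not mean a stronger response there, since the 13 include genes that fell past the threshold in the WT isolate alone. Of the 24 genes, 7 had changed in the non-WT isolate alone, 5 in the WT isolate alone, 6 in both in the same direction and 6 in both in opposite directions.

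B9J08_004161, on scaffold 7 from 185008 to 186561 on the plus strand, had the largest higher effect in the non-WT isolate. It rose there from 10.4 ± 1.28 to 33.9 ± 8.78 CPM and stood at 7.06 ± 0.17 and 5.55 ± 0.86 CPM in the WT isolate, a difference in log2 fold change of 2.05 (SE 0.28, edgeR interaction, adjusted p = 0.0247). B9J08_003737, on scaffold 1 from 2369962 to 2371053 on the minus strand, rose in both isolates, from 219 ± 15.9 to 782 ± 85.9 CPM in the non-WT and from 712 ± 2.04 to 1097 ± 164 CPM in the WT isolate, a difference of 1.21 (SE 0.16, edgeR interaction, adjusted p = 0.0247). B9J08_001012, the gene of scaffold 3 described above, rose less in the non-WT isolate, from 65.0 ± 15.1 to 108 ± 15.3 CPM, a difference of -1.49 (SE 0.24, edgeR interaction, adjusted p = 0.0423). B9J08_004863, on scaffold 6 from 910747 to 911031 on the plus strand, rose from 740 ± 20.6 to 1184 ± 78.7 CPM in the non-WT and from 57.4 ± 0.38 to 228 ± 42.5 CPM in the WT isolate, a difference of -1.31 (SE 0.16, edgeR interaction, adjusted p = 0.0246). Without untreated non-WT replicate 1 or 2, 0 genes passed the edgeR interaction test, with 582 and 668 genes at an unadjusted p under 0.05. The 4 differences kept their direction and similar sizes. In the order given, they were 1.94, 1.15, -1.23 and -1.33 without replicate 1. Without replicate 2 they were 2.19, 1.29, -1.71 and -1.28. The count moved from 24 to 143 with DESeq2, 7 with limma-voom and 0 with glmTreat against a fold change of 1.5, where 50 genes had an unadjusted p under 0.05 in edgeR. It was 4 and 10 without treated non-WT replicate 1 or 2, 9 and 195 without untreated WT replicate 1 or 2, and 2 without treated WT replicate 2. Of the interaction calls, 54.2% had a higher signed log2 fold change in the non-WT isolate with TMM factors against 35.7% with library size alone.

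**Figure D2:**
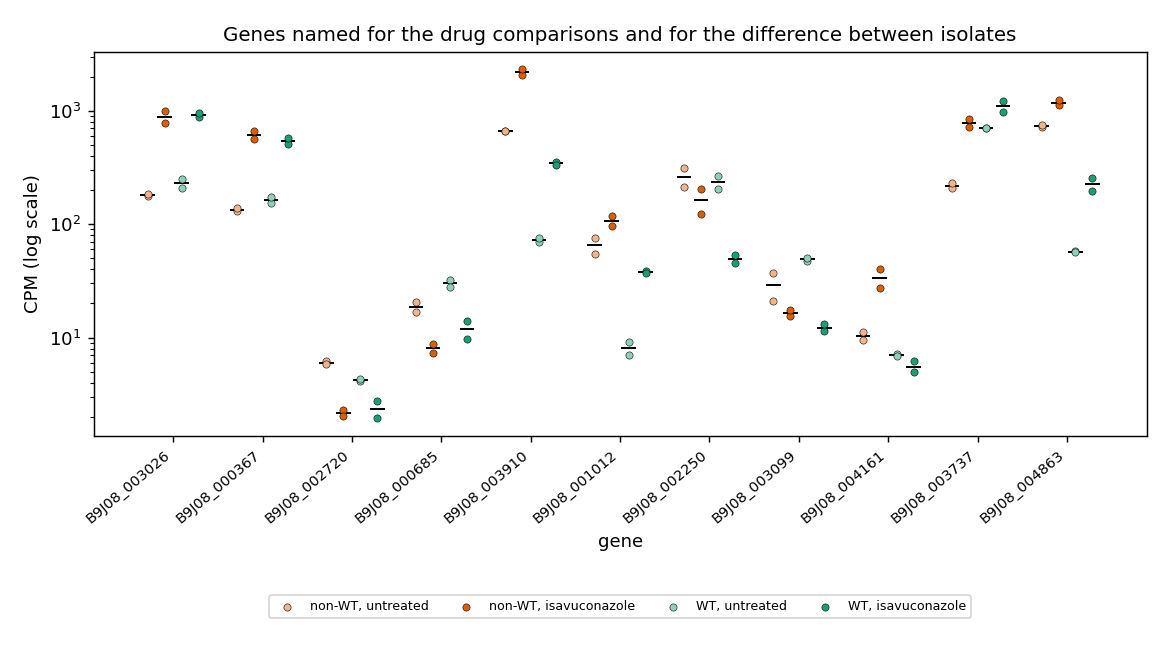
CPM on a log axis of the 11 genes named for the drug comparisons and for the difference between isolates; points are libraries, with 2 per group, and lines are group means. B9J08_003026 and B9J08_000367 rose in both isolates, by log2 fold changes of 2.29 and 2.19 in the non-WT and 2.0 and 1.73 in the WT isolate, while B9J08_004161 rose in the non-WT isolate and stood at 7.06 and 5.55 CPM without and with drug in the WT isolate.

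The third question was how the isolates differed without drug. In the non-WT isolate 1423 genes were higher and 1551 lower than in the WT isolate, 55% of the genes tested. With library size alone the balance turned, to 1561 higher and 1413 lower. Differences of at least 2-fold were found for 140 genes that were higher and 296 that were lower. A pair of adjacent genes at the end of scaffold 11 had 0 counts in all 4 WT libraries. B9J08_005564, from 48797 to 50563 on the minus strand, stood at 175 ± 7.25 CPM in the untreated non-WT isolate, at least 956-fold higher than the limit set by 3 counts in a WT library (edgeR adjusted p = 4.96e-09). B9J08_005565, from 55065 to 57107 on the minus strand, stood at 12.9 ± 0.53 CPM, at least 70.5-fold higher (edgeR adjusted p = 6.14e-07). They are the genes 19 and 20 of the 20 on the scaffold, of which 18 were tested. The other 16 tested genes of scaffold 11 had counts in every WT library and a median log2 difference of -0.32 between the non-WT and the WT isolate, with a range from -2.87 to 2.65. The pair adjoins 2 genes that were also higher in the non-WT isolate, which were chosen after their values were seen. The gene at 43777 to 45189 was higher by 2.65 (SE 0.14, edgeR adjusted p = 3.72e-07) on the log2 scale. The gene at 46320 to 47672 was higher by 1.43 (SE 0.31, edgeR adjusted p = 0.00264). No gene with at least 50 counts in every WT library was at 3 counts or fewer in all non-WT libraries. Among genes lower in the non-WT isolate, B9J08_002244, on scaffold 9 from 20794 to 21267 on the plus strand, stood at 7.70 ± 0.32 CPM against 120 ± 7.36 in the WT isolate, a log2 difference of -3.96 (SE 0.09, edgeR adjusted p = 3.64e-09). B9J08_004930, on scaffold 2 from 83168 to 85018 on the plus strand, stood at 178 ± 27.9 against 2004 ± 816 CPM, a log2 difference of -3.49 (SE 0.27, edgeR adjusted p = 3.09e-06). No large scaffold differed as a whole, since the largest median log2 difference among the 10 scaffolds with at least 100 tested genes was 0.03 in size.

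**Figure D3:**
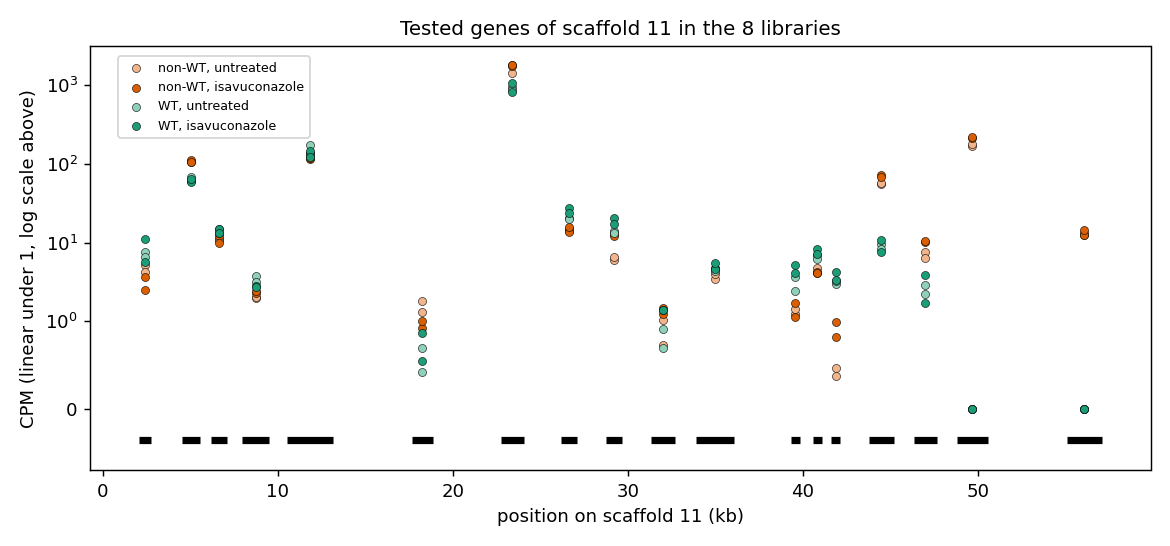
CPM of the 18 tested genes of scaffold 11 in the 8 libraries by position in kb; points are libraries, black bars the genes, and the y axis is linear under 1 CPM and logarithmic above. The last 2 genes, B9J08_005564 and B9J08_005565, have points at 0 for all 4 WT libraries and lie at 12.5 CPM or higher in the non-WT libraries.

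The isolates were compared again under isavuconazole. With drug, 1383 genes were higher and 1567 lower in the non-WT isolate, and 161 and 323 of them differed at least 2-fold. The same 1074 genes were higher and the same 1267 lower as without drug, where independent lists would share 364 and 450, and 8 genes changed sides. Across genes, the differences without and with drug, measured on separate libraries, had a Pearson r of 0.93. B9J08_005564 stood at 219 ± 5.34 CPM, at least 1609-fold higher than the limit in the treated WT libraries (edgeR adjusted p = 4.82e-09), and B9J08_005565 at 13.5 ± 1.21 CPM, at least 99.2-fold higher (edgeR adjusted p = 3.09e-07). B9J08_003981, on scaffold 1 from 2916752 to 2918401 on the minus strand, stood at 11.1 ± 3.06 CPM in the treated non-WT against 102 ± 6.77 in the treated WT isolate, a log2 difference of -3.19 (SE 0.19, edgeR adjusted p = 4.90e-07). B9J08_002244 remained lower, at 15.0 ± 0.87 against 127 ± 2.07 CPM, a log2 difference of -3.08 (SE 0.09, edgeR adjusted p = 6.46e-09). Without treated non-WT replicate 1, 907 genes were higher. Each class of susceptibility is held by a single isolate, so these comparisons concern the isolates and not the classes.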

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

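The tests on the genes of scaffold 11, the bootstrap interval and the repeated thinning were chosen only after the results were seen. The effect of isavuconazole differed between the isolates for 24 genes by the edgeR interaction test, against 763 of 5406 genes at an unadjusted p under 0.05. If no effect differed, a share of about 0.05 of the genes would be expected there on average, and 763 is well above it. With 2 libraries per group, deviations that many genes share within a library can also raise that number. It therefore does not show that genes beyond the 24 differ, though some may. The number of interaction calls also depended on the libraries kept, as given above. The difference in log2 fold change, non-WT minus WT, was 2.05 for B9J08_004161, 1.21 for B9J08_003737, -1.49 for B9J08_001012 and -1.31 for B9J08_004863, and each is listed because the test of the difference itself passed the threshold.

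The lists of the isolates differed far more than the interaction test, with 1257 genes past the threshold in a single isolate, of which 12 had an interaction call. Of the 1257 genes, 82.7% had the same direction in the other isolate, against 73.8% of all 5406 genes. The latter include the 1257 genes and those that passed in both isolates. A threshold that parts genes with similar responses may account for some of them, but agreement in direction is not agreement in size. The median log2 change was 0.37 where they passed and 0.13, signed by that direction, in the other isolate. What equal responses would give after such a selection was not simulated, so how many are of this kind cannot be told. A response confined to 1 isolate is argued against for the genes as a set, since their median change in the other isolate was 0.36 times that in the isolate where they passed (95% bootstrap interval over genes 0.33 to 0.39). That interval resamples genes, so it does not cover deviations that many genes share within a library, nor the spread between cultures. The WT count exceeded the non-WT count by a factor of 1.40, and still by 1.36 with every library thinned to 14.5 M counts (1.31 to 1.35 in 10 more draws), which argues against depth as the whole cause. The excess held with RLE factors, at 1446 genes in the WT and 1040 in the non-WT isolate. With library size alone the counts were nearly equal, at 1445 and 1439. Which isolate had the longer list also changed when single libraries were left out. With the 4 libraries of each isolate fitted alone the factor was 0.55, so the larger WT list may come from the single spread assumed for both isolates. A true difference in response, which the design also allows, stays open.

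The absence of counts for the 2 adjacent genes of scaffold 11 in the WT isolate held in both treatments. Too little depth is argued against, since the non-WT level predicts at least 212 counts in each WT library for either gene. A mix-up of single libraries is argued against as well, by the counts themselves, since it would leave counts in a library labelled WT. All 4 WT libraries were at 0, while every non-WT library held at least 177 counts of each gene. On the 5388 tested genes of other scaffolds, all 8 libraries correlated better with each library of their own isolate (r of 0.983 or more) than with any of the other (0.954 or less). The first principal component had already parted the isolates, so these correlations add little. With 0 counts over the 4 WT libraries, a deletion in the WT isolate, a WT sequence too different for its reads to be counted, and silent genes cannot be told apart, because neither aligned reads nor a WT genome was used here.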

How the results depend on the processing

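The alternatives added after the data were seen were limma-trend on the deposited log2 values, thinning, leaving out genes with a restored count and the crossed block. The gene list tests could not be run, since no list member could be matched to an identifier, and the pseudocount does not apply to counts. No interaction can be had from the 4 libraries of a comparison. The named genes gave 439 values under the alternatives. Of these, 417 kept direction and side of the threshold, 22 kept the direction alone and 0 reversed. DESeq2 gave no adjusted p for B9J08_002720 in the non-WT isolate, and that value is not among the 439. The calls lost were B9J08_000685 in the non-WT isolate under glmTreat (adjusted p = 0.123, range 1.80e-07 to 0.123 over its alternatives) and interaction calls, of which B9J08_001012 lost 9 of 21 and each of the other 3 lost 4 of 21. The remaining counts stayed within 1.5 times the main count. The cause was not tested for any of the changes below unless stated.

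With library size alone, 1098 genes fell in the non-WT isolate, 504 fell in both isolates, 15 went in opposite directions and 18 interaction genes were lower. Relative to TMM, that scaling shifted the median log2 fold change by -0.09 in the non-WT and -0.04 in the WT isolate. Upper quartile factors gave 6 lower interaction genes, DESeq2 84 higher and 59 lower, limma-voom 4 higher and 3 lower, and thinning 20 higher. The 4 libraries of the comparison alone gave 804 genes that rose in the non-WT isolate, and 462 that rose and 406 that fell in the WT isolate. By construction, a fold change of at least 1.5 left fewer genes. In the non-WT isolate 154 rose and 110 fell, in the WT isolate 144 rose and 121 fell, 69 rose and 37 fell in both and 1 went in opposite directions. Without drug 422 were higher and 745 lower in the non-WT isolate, and with drug 408 and 762. The stricter glmTreat test left 36 that rose and 2 that fell in the non-WT isolate, 30 and 10 in the WT isolate, 17 that rose in both, 0 that fell in both and 0 in opposite directions. It called 204 higher and 422 lower without drug, 217 higher and 435 lower with drug, and 0 higher and 0 lower interaction genes in edgeR, with 50 genes at an unadjusted p under 0.05.

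With the replicate block, 667 genes rose and 704 fell in the non-WT isolate, 898 rose and 869 fell in the WT isolate, 77 were higher and 88 lower in the interaction, 25 went in opposite directions, and 2961 and 2953 genes differed between isolates without and with drug. The deviations of libraries with the same replicate number had correlations of -0.04 between untreated and treated non-WT and 0.33 between untreated and treated WT libraries, and 2 pairs are too few to show pairing. Between the untreated isolates the correlation was -0.11, and the crossed replicate block gave 1487 higher and 1591 lower genes.

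Leaving out each library in turn, with a lone library assumed to vary like the other groups, gave 225 to 653 genes that rose and 126 to 640 that fell in the non-WT isolate, 485 to 732 and 416 to 660 in the WT isolate, and 0 to 79 higher and 0 to 116 lower interaction genes. It gave 966 to 1423 higher and 1228 to 1591 lower genes without drug, 907 to 1478 and 1207 to 1641 with drug, 152 to 349 that rose in both isolates, 82 to 299 that fell in both and 2 to 33 in opposite directions. Both ends for the interaction came from untreated libraries, with 0 genes without either non-WT library and the highest counts without WT replicate 2. At this depth and with 2 libraries per group, the simulated interaction recovered 35 of 67 genes changed by a factor of 1.5. Differences of that size between isolates can therefore be missed, and larger ones may be too. With all 8 libraries, 24 genes passed the edgeR interaction test. B9J08_002250 did not, at a difference in log2 fold change of 1.58 (SE 0.33, edgeR interaction, adjusted p = 0.0738). Nor did B9J08_003099, at 1.19 (SE 0.30, edgeR interaction, adjusted p = 0.110).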

Other observations

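All tests in this part were chosen after the main results were seen. Genes that differed between isolates lay near scaffold ends more often than elsewhere. Within 20 kb of the outermost genes of the 10 large scaffolds, 29 of 158 genes (18.4%) differed at least 2-fold without drug, against 7.62% of 5200 other genes (permutation test by 10000 circular shifts of the calls, one-sided, p = 0.0011, adjusted 0.00275), with 11 higher and 18 lower in the non-WT isolate. With drug the shares were 19.6% and 8.54% (permutation p = 6e-04, adjusted 0.00275). For changes of at least 2-fold after isavuconazole, with 2 genes near the ends in the non-WT and 1 in the WT isolate, no excess was detectable. The shares were 1.27% against 0.79% in the non-WT isolate (permutation p = 0.358, adjusted 0.597) and 0.63% against 0.75% in the WT isolate (permutation p = 0.695, adjusted 0.869). Whether the excess differs between the drug and the isolate comparisons was not tested. The adjustment is over 5 comparisons, including the interaction, in which 0 of the 158 genes and 8 of the 5200 others differed at least 2-fold.

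The responses of neighbouring genes to the drug were correlated, and so were their differences between the isolates. Across 1313 pairs of adjacent genes transcribed away from each other, the Spearman rho of their log2 fold changes was 0.22 in the non-WT and 0.21 in the WT isolate. It was 0.17 and 0.19 for 2763 pairs on the same strand, and 0.14 and 0.16 for 1315 pairs transcribed toward each other, with a median gap of 94 bp (p = 1e-04 each, the smallest that 10000 permutations of gene order can give, and 0.000115 adjusted over 15 such tests). Runs of at least 4 adjacent genes that changed in the same direction numbered 14 in the WT isolate, against a mean of 2.88 in 2000 shuffled orders (p = 5e-04, the smallest these permutations can give, adjusted over 5 comparisons 0.000833), and 4 in the non-WT isolate, against 0.76 (permutation p = 0.0055, adjusted 0.00687). The longest of these runs held 7 genes that rose in the WT isolate, on scaffold 1 from 3084823 to 3096522, by 0.24 to 0.50 on the log2 scale (permutation p = 0.0115 for a run as long, which did not hold after adjustment, 0.0575). The pattern was not particular to the drug. For the isolate difference without drug, rho was 0.17 for pairs transcribed away from each other, 0.12 on the same strand and 0.08 toward each other. With drug it was 0.16, 0.11 and 0.08, and for the interaction 0.12, 0.10 and 0.12. Runs numbered 81 without and 79 with drug, against 44.8 and 44.0 in shuffled orders, and 0 for the interaction. The strand setting of the counts is not given in the sources used here, and reads that reach into a neighbouring gene were not separated here.

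Genes that isavuconazole lowered in both isolates were already lower in the untreated non-WT than in the untreated WT isolate. The 275 genes had a median log2 difference of -0.30 (quartiles -0.68 and -0.01), with 154 lower and 25 higher past the threshold, and with drug the median was -0.29. Noise of the shared untreated libraries is argued against, since the 514 genes picked by the non-WT drug comparison alone, where such noise pushes the difference upward, had a median of -0.21 (95% bootstrap interval over genes -0.27 to -0.15), the 684 picked by the WT comparison alone had one of -0.12 with drug, where noise of the treated libraries pushes upward too, and 20 simulations with the drug effects and no isolate difference gave medians of -0.0031 to 0.022. The interval resamples genes and the simulations draw each gene independently, so neither covers deviations that many genes share within a library. Expression level is argued against too, since 0% of 10000 lists matched on expression had a median as low, the lowest being -0.14. No biological explanation was tested, and each class is held by 1 isolate. For the 318 genes that rose in both isolates the median was 0.08, with 110 higher and 88 lower. Shared noise stays open there, since the 509 genes picked by the non-WT comparison alone had a median of 0.054 (interval 0.0031 to 0.10) and the 752 genes picked by the WT comparison alone one of -0.0014 with drug, and library size alone shifts the untreated difference of all genes by 0.031. Expression level may also account for it, since 7.22% of matched lists had a median as high.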
